A study of Mus musculus with 11 samples.

How the data were processed

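RNA sequencing covered 9 mouse libraries in 3 groups of 3: control villus, Cdx2-del ISC and control ISC. CDX2 chromatin immunoprecipitation covered 1 library of pooled ISC from mice not given tamoxifen, the drug that activates the deletion. Per the labels, the mice of all 9 RNA libraries, controls included, were given tamoxifen at 1 to 2 mg for 4 to 5 days. The labels give the genotype of control ISC as Cdx2+/+. Per the labels' protocols, ISC RNA was polyadenylated RNA prepared with one kit, and villus RNA was total RNA prepared with another, on another instrument and with longer reads. The input library of the immunoprecipitation was not analysed. The labels call the 3 libraries of a group biological replicates.

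The expression table holds log2 values that the authors deposited as log2(FPKM + 1) per gene, where FPKM is fragments per kilobase and per scaled library total. The submitters' processing notes name Bowtie, TopHat2 2.0.9, Cufflinks 2.1.1, Cuffnorm, Cuffdiff and the mm9 build without giving their roles, and the library scaling is not given in the sources used here. The deposited annotation holds 23953 transcripts, shortened to their 3′ ends (74% of them lie near the longest annotated length), and 8.01% of them have fewer than 200 annotated bases. The table holds 23895 genes, all in that annotation. Because features this short hold few reads, their FPKM values are large per read and unstable.

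Among genes of the most common annotated length, low values up to 30 reads fell on whole multiples of 1 step per library (within 0.05 of a read) for 99.2 to 99.9% of values. Reads were recovered from these steps to give depth, and the step is what a single read is worth. Recovered reads serve as an alternative and not as the main values, because they cover genes of the most common annotated length alone.

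A deposited table of the authors' own comparisons gives a log2 fold change with 1 added to each group, p-values and q-values for 3 pairs of groups, as deposited by the authors with the layout of Cuffdiff. Its 2 columns of group means were not used. The peak list gives a position and a score for each peak. The score is deposited by the authors as their peak caller wrote it, the peak names begin with MACS per the file, and the version, settings, use of the input and scale of the score are not given in the sources used here.

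The columns of the expression table name a group and a number that starts at 0 and is not stated to be the replicate number of the labels, so a column stands for a library of its group and libraries were not paired across groups. Values were returned to FPKM and put on log2(FPKM + 1), with a pseudocount of 1, so that fold changes on that scale understate those of low genes. Genes with FPKM of at least 1 in 3 or more of the 6 libraries compared were tested with limma 3.58.1 (R 4.3.3), with moderated variances that follow a trend on mean level, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Only the 6 libraries of the comparison entered each fit. Fold changes printed with FPKM are ratios of group means, and log2 differences are from the fit. No fold is given against a group listed at 0.

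Gene lists for cell types, pathways and library checks were fixed before the data were examined, as were the tests of the comparisons apart from the 4-fold peak test, the alternatives other than those named last below and the rule for named genes. That rule takes, per comparison, the 10 largest differences in each direction among calls whose groups do not overlap and whose mean FPKM in the higher group is at least 2, then Cdx2, then up to 4 members with the smallest p of each list that passes or holds a called member. For peaks it takes up to 5 called genes per direction with a peak within 50 kb and the 5 highest scores. The result of a single gene under this rule is left out, and some others are given only within counts. Apob, Mogat2, Fxyd3, Cdx1, Hnf4a, Lyz1, Itln1 and Atp4a fall outside it and were chosen after their values were seen. If fewer than 5 genes had been called in a direction, the 5 with the smallest unadjusted p would have been named. Lists with at least 3 tested genes went to limma's camera with a preset correlation of 0.01, with an estimated correlation as an alternative, and to fry, which asks whether a list's genes move on balance one way. The 27 lists covered intestinal stem cells, position 4 or reserve stem cells, Wnt targets, cell cycle, enterocyte, Paneth, goblet, enteroendocrine and tuft cells, Notch and secretory commitment, stomach, squamous foregut, proximal and distal intestine, intestinal transcription factors, reported CDX2 targets, cholesterol synthesis, p53 targets, interferon response, epithelial antimicrobial genes, immediate early genes of dissociation stress, leukocytes, stroma and endothelium, erythroid cells, sex, ribosomal proteins and replication histones. The lists for stroma and endothelium, erythroid cells and squamous foregut had too few tested genes.

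Peak midpoints were assigned to a gene when within 50 kb of its annotated part, and shares were compared by Fisher's exact test (two-sided), with genes tested in the comparison as background. Medians of genes near peaks were set beside 10000 random lists matched on mean expression. Villus-high and ISC-high genes were defined as those called with at least a 4-fold difference. The peak test for these groups was first run on all calls, and the 4-fold calls were run after those values were seen, so both are given. For the simulations with shared controls, normal values were drawn 100 times around the group means with the spread of each gene, with Cdx2-del ISC at the control mean. Each gene was drawn independently, so shifts that the genes of a library share were not simulated. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used for the annotation, peaks and figures. Wilson intervals are at the 95% level and cover counting error only.

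The fit was tested on simulated data made from the means and variances of the real genes, with 50 genes changed at each size. For Cdx2-del against control ISC (11883 genes) it recovered 4% of genes changed by 1 on the log2 scale, 40% of those changed by 2, 82% of those changed by 3 and 78% of those changed by 4, and called 0.009% of unchanged genes. For villus against control ISC (12011 genes) the shares were 10%, 64%, 86% and 82%, and 0.059%. With so few genes changed, adjustment was stricter in this simulation than in the villus data, where 7876 genes were called. The simulated villus shares therefore do not describe the real villus comparison. In the Cdx2-del simulation most 2-fold changes in single genes were not called with 3 libraries per group.

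Alternatives covered the pseudocount, the filter on low values, quantile and median scaling, the libraries in the fit, the trend, a 2-fold minimum, each library left out in turn, the peak distance and score, and the correlation of list tests. Added after the data were seen were the sex of the library as a covariate, the removal of features under 200 bases, library weights, limma voom on recovered reads, and leaving out libraries for the results on peaks and on villus-high genes.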

Results

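The series addressed what the homeodomain transcription factor CDX2, a master regulator of intestinal identity, does in stem cells at the base of the mouse intestinal crypt and in differentiated cells of the villus. RNA was sequenced from 3 libraries of control villus epithelium, 3 of control intestinal stem cells (ISC) and 3 of ISC labelled as deleted for Cdx2 (Cdx2-del ISC). The stem cells had been sorted from proximal small intestinal crypts for high GFP driven by Lgr5, a Wnt receptor component and marker of these cells, and the villus cells were unsorted jejunal epithelium. CDX2 binding in ISC came from 1 chromatin immunoprecipitation library of pooled cells, with no replicate, and the peak list was the file used from it. The input library of that experiment was not analysed here. Libraries are numbered 0 to 2 within each group as in the deposited table.

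Over genes of the most common annotated length, the reads recovered per library came to 2641574, 3961239 and 725769 in villus, 4131038, 7179906 and 5417163 in Cdx2-del ISC, and 5776247, 4351601 and 4381979 in control ISC. A single read in such a gene was therefore worth 0.689 FPKM in villus library 2 and 0.0398 FPKM in Cdx2-del library 1, so low villus values were the least precise. Across genes, log2 values correlated at r = 0.965 to 0.974 between villus libraries, 0.902 to 0.933 between control ISC libraries and 0.872 to 0.904 between Cdx2-del libraries. Genes are not independent replicates, and these r values describe the libraries. Cdx2-del library 1 and control ISC library 2 expressed Xist, at 33.9 and 94 FPKM, with Ddx3y, Eif2s3y, Kdm5d and Uty listed at 0, and the other libraries showed the Y-linked genes.

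Cdx2 itself, on chromosome 5 (148112476 to 148113476, mm9), was measured at 257 ± 73.4 FPKM in Cdx2-del ISC (SD, n = 3), 185 ± 13.9 in control ISC and 330 ± 67.9 in villus. The log2 difference between Cdx2-del and control ISC was 0.44 (SE 0.26, limma adjusted p = 0.836). The deposited annotation covers the 3′ end of the transcript alone, and the labels do not say which exon was removed, so this level does not check the deletion. Its paralog Cdx1 stood at 136 ± 81.6 FPKM in the libraries labelled Cdx2-del and 134 ± 57.3 in control ISC. Villus exceeded control ISC in Cdx2 by 0.81 on the log2 scale (SE 0.21, limma adjusted p = 0.00866), a difference that became -0.04 after quantile normalization and -0.14 with limma voom on recovered reads.

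The comparison of the libraries labelled Cdx2-del with control ISC asks which stem cell transcripts depend on CDX2. Of 8 tested genes of a stomach list, 3 were called, all higher in Cdx2-del ISC, and the list as a set passed with a preset but not with an estimated correlation (limma camera adjusted p = 0.0612). With an estimated correlation 0 of 24 lists passed in villus either, although all 40 enterocyte genes were called there. Not passing it, here and below, therefore does not show that a list is unchanged. Gkn3, a gastrokine of the stomach, rose from 154 ± 62.8 to 2230 ± 963 FPKM (SD, n = 3), 14.4-fold. Its mean in villus was 2.4 FPKM, so control ISC already held this transcript. Pgc, the precursor of the gastric protease pepsin C, rose 21.7-fold from 14.9 ± 9.02 to 322 ± 193 FPKM, and Vsig1, a junctional protein of gastric epithelium, rose 23.4-fold from 1.62 ± 0.953 to 37.9 ± 7.74 FPKM. Pgc and Vsig1 were each called in 2 of the 6 limma fits that left out a library (adjusted p up to 0.145 and 0.103), and Gkn3 in 5. Clu, a secreted chaperone, rose 46.1-fold to 93.1 ± 28.7 FPKM, and the septin gene Sept5 fell 6.99-fold from 466 ± 45.3 to 66.6 ± 17.1 FPKM.

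In all, 19 of 11883 tested genes were called (limma on log2(FPKM + 1), Benjamini-Hochberg adjusted p under 0.05), 13 higher and 6 lower, and each differed at least 2-fold. The balance of directions was not stable, with 6 higher and 7 lower without Cdx2-del library 0, 6 and 8 without library 1, 5 and 4 without library 2, 7 and 2 without control library 0, 9 and 1 without control library 1, and 8 and 2 without control library 2. The largest rises among called genes measured above 0 in both groups were those of Wfdc18, a small secreted WAP domain protein (94.7-fold, log2 difference 5.24, SE 0.52, limma adjusted p = 0.0109), Clu (5.00, SE 0.43, adjusted p = 0.00844) and the sulfotransferase Sult1c2 (4.90, SE 0.54, adjusted p = 0.0158). Pgc (4.30, SE 0.55, limma adjusted p = 0.0346), the sodium-proton exchanger Slc9a4 (4.22, SE 0.54, adjusted p = 0.0346), the monooxygenase Fmo1 (3.98, SE 0.35, adjusted p = 0.00844), Vsig1 (3.94, SE 0.44, adjusted p = 0.0158) and Gkn3 (3.83, SE 0.39, adjusted p = 0.0114) followed. The selenium carrier Sepp1 rose 6.02-fold, and Fxyd3, Scarb1 and Foxq1 made up the remaining higher calls apart from Snord52. Snord52, a small nucleolar RNA annotated over 59 bases on chromosome 17 (35087895 to 35087953), was listed at 0 in each control ISC library and averaged 5140 ± 4000 FPKM in Cdx2-del ISC.

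Lower calls besides Sept5 (log2 difference -2.82, SE 0.26, limma adjusted p = 0.00844) were the kinase gene Camk1d (7.46-fold, -2.83, SE 0.32, adjusted p = 0.0185), AI747448 (7.13-fold), the urea transporter Slc14a1 (4.22-fold) and the protein kinase inhibitor Pkig (3.22-fold). Defa17, an alpha-defensin of Paneth cells on chromosome 8 (22766239 to 22767208), was listed at 0 in each Cdx2-del library and at 1270, 423 and 10300 FPKM in the control ISC libraries. Its value is uncertain because alpha-defensin genes are near-identical copies that can share reads.

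**Figure D1:**
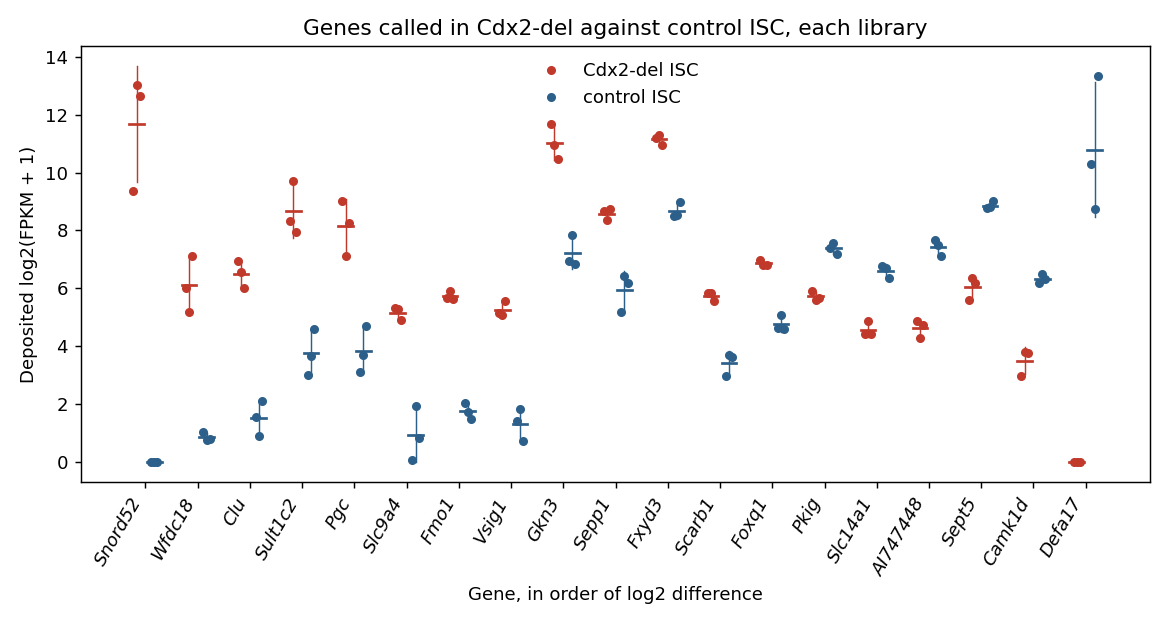
Deposited log2(FPKM + 1) of each of the 19 called genes (horizontal axis, in order of log2 difference) in the 3 Cdx2-del and 3 control ISC libraries; points are libraries, horizontal bars means and vertical bars SD. Gkn3 averages 2230 FPKM in Cdx2-del and 154 in control ISC, and Snord52 and Defa17 are listed at 0 in every library of 1 group.

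Of the 21 stomach genes in the table, 8 were expressed enough to test. Gkn3, Pgc and Vsig1 rose, 4 passed when adjusted over the list alone (with the water channel Aqp5, 30.6 ± 37.3 against 0.162 ± 0.194 FPKM, adjusted p = 0.254 over all genes), and the median log2 difference of the 8 was 3.02. Over all 21 genes, tested or not, the mean log2 value was 2.22 ± 0.29 in Cdx2-del and 1.18 ± 0.18 in control ISC (SD, n = 3), a difference of 1.05. limma's camera placed the list higher with its preset correlation (adjusted p = 2.00e-09), and the adjusted p was 0.0612 with an estimated correlation. The proximal intestine list had 6 of 7 members with positive differences (median 0.73, camera adjusted p = 0.000257, adjusted p = 0.162 with an estimated correlation). Its leading members were the duodenal iron genes Cybrd1 (9.32 ± 3.71 against 0.214 ± 0.319 FPKM, limma adjusted p = 0.101) and Slc40a1 (15.0 ± 2.00 against 2.39 ± 0.951 FPKM, adjusted p = 0.144), and 3 members passed when adjusted over the list alone. Cybrd1 and, in the stomach list, Aqp5 passed the filter on low values through the Cdx2-del libraries alone. Such members push the tests of their lists upward. In the distal intestine list 1 of 5 tested members had a positive difference, with a median of -0.37 (limma camera adjusted p = 0.883).

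Each of the 29 tested cell cycle genes had a negative difference in Cdx2-del ISC (median -0.53), and none passed singly. Examples are the replication licensing genes Cdt1 (49.7 ± 17.3 against 95.4 ± 9.77 FPKM, limma adjusted p = 0.505) and Mcm6 (151 ± 20.5 against 243 ± 28.8 FPKM, adjusted p = 0.518). The list passed camera with the preset correlation (adjusted p = 3.22e-07), with adjusted p = 0.162 with an estimated correlation. Replication histone genes had 44 of 45 negative differences (median -0.70, camera adjusted p = 8.09e-06, adjusted p = 0.372 with an estimated correlation). The mean log2 value of the histone list overlapped between the groups, at 2.481, 2.38 and 1.367 in Cdx2-del libraries 0 to 2. It was 3.386, 2.467 and 2.305 in control ISC libraries 0 to 2. The histone list was fixed as a check of libraries and is not taken as a measure of proliferation. Enteroendocrine genes had a median of -0.75 (camera adjusted p = 6.47e-05, adjusted p = 0.372 with an estimated correlation). None of these 21 passed over all genes, and 4 passed when adjusted over the list alone: the endocrine transcription factor genes Insm1 (9.47 ± 0.562 against 34.8 ± 7.82 FPKM), Neurod1, Pax4 and Neurog3. The mean log2 value of the enteroendocrine list overlapped between the groups (3.042 to 4.032 against 4.015 to 4.803 per library). The Notch and secretory commitment list, with Hes1, Hes6 and Dll1, had 10 of 12 negative differences (median -0.68, camera adjusted p = 0.000477, adjusted p = 0.372 with an estimated correlation). Tuft cell genes had 12 of 13 positive differences (median 0.79, camera adjusted p = 2.61e-05, adjusted p = 0.372 with an estimated correlation), among them Rgs13 (37.0 ± 15.1 against 9.75 ± 5.28 FPKM, limma adjusted p = 0.364) and the kinase Dclk1. The tuft list also overlapped in mean log2 value (3.052 to 3.504 against 2.133 to 3.149 per library).

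Among 16 genes reported elsewhere as CDX2 targets, 14 had negative differences (median -0.55, camera adjusted p = 0.00163, adjusted p = 0.372 with an estimated correlation), and none passed over all genes. Isx, an intestinal homeobox gene, stood at 9.17 ± 5.08 against 66.1 ± 2.41 FPKM (7.21-fold, limma adjusted p = 0.0621), and the brush border phosphatase Alpi at 60 ± 9.67 against 15.4 ± 4.98 FPKM (adjusted p = 0.0914); both passed when adjusted over the list alone. Immediate early genes, a sign of stress during tissue dissociation, had 9 of 12 positive differences (median 0.53, camera adjusted p = 0.000442, adjusted p = 0.372 with an estimated correlation), and none of them passed over all genes. When adjusted over the list alone 2 passed, Atf3 and Zfp36, and the mean log2 value of the list overlapped between the groups (7.56 to 8.08 against 6.96 to 7.81 per library). Stem cell genes gave 1 call in 24, Slc14a1, with 11 positive and 13 negative differences (limma camera adjusted p = 0.286). That test asks for a shift in 1 direction. The mixed test of fry, which counts changes in both directions, gave adjusted p = 0.00133. The authors' deposited comparison marks 3 of these genes as higher and 7 as lower. Lgr5 stood at 102 ± 14.1 against 157 ± 43.9 FPKM.

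The count of 19 calls fell to 9 without Cdx2-del library 2 and without control library 0, and to 10 without control library 1 and without control library 2, and was 53 with all 9 libraries in the limma fit, 6 without a trend and 0 with no filter on low values (967 genes at unadjusted p under 0.05, where 796 would be expected). It was 35 without features under 200 bases and 34 with library weights, and Clu, Fmo1, Sept5 and Wfdc18 were called whichever single library was left out. Foxq1, Pkig, Scarb1 and Slc14a1 were called in none of these 6 fits, Sepp1 and Slc9a4 in 1, and Camk1d, Fxyd3, Pgc and Vsig1 in 2, with no change of sign.

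The comparison of villus with control ISC sets unsorted villus epithelium beside sorted stem cells. Their libraries also differed in preparation, so the differences below cannot be assigned to cell type alone. Enterocyte genes were higher in villus throughout: all 40 rose, by a median of 6.16 on the log2 scale. The brush border peptidase Anpep rose 191-fold from 60.2 ± 6.66 to 11500 ± 950 FPKM (SD, n = 3), the cholesterol uptake protein Npc1l1 266-fold to 1990 ± 179 FPKM, and Alpi 180-fold to 2770 ± 528 FPKM. Stem cell genes were lower, with 24 of 24 called and a median of -3.68. The Wnt-responsive transcription factor gene Ascl2 fell 88.0-fold from 123 ± 23.8 to 1.40 ± 0.804 FPKM, and the adhesion receptor Cd44 fell 37.5-fold. Lgr5, at 1.61 ± 0.432 against 157 ± 43.9 FPKM, was the gene used for sorting and is no finding.

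Proliferation genes were also lower in villus. All 29 tested cell cycle genes fell (median -2.99), among them the replication helicase subunit genes Mcm5 (41.3-fold) and Mcm7 (19.1-fold, limma adjusted p = 1.93e-06). In the replication histone list, fixed as a check of libraries, 30 of 41 genes fell and 1 rose (median -3.15). Wnt targets gave 11 lower calls in 13 tested, with Axin2, a feedback inhibitor of the pathway, 13.6-fold lower. The Notch and secretory commitment list gave 7 lower calls in 11, with the receptor Notch1 29.1-fold and the glycosyltransferase Lfng 51.7-fold lower. Ribosomal protein genes gave 70 lower calls in 77 tested and 1 higher (median -2.24), for example Rpl37 at 240 ± 48.8 against 4500 ± 1570 FPKM. Paneth genes gave 11 lower calls and 1 higher in 17, and the higher one, Defa24, belongs to the alpha-defensins whose reads cannot be assigned with certainty.

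Interferon response genes were higher in villus, with 9 higher calls in 10 (median 3.33), including Isg15 (50.6-fold) and Irf7 (13.4-fold). Of the epithelial antimicrobial genes 8 of 9 rose and 1 fell, with the lectin Reg3b at 15100 ± 4120 against 214 ± 197 FPKM. Leukocyte genes gave 9 higher calls in 12, led by the lymphocyte protease Gzmb at 47.9 ± 25.6 against 0.641 ± 0.694 FPKM, and Ptprc was at 3.78 ± 1.12 FPKM in villus and listed at 0 in control ISC, so the unsorted villus preparations held leukocyte transcripts. All 6 tested distal intestine genes rose, with the ileal bile acid binding protein Fabp6 at 5850 ± 4740 against 3.94 ± 3.49 FPKM. Reported CDX2 targets gave 14 higher calls in 16 (median 4.00). Among intestinal transcription factors 9 rose and 5 fell (median 0.54, or -0.20 after quantile normalization), with Hnf4g 16.6-fold and Creb3l3 51.4-fold higher. This list, the p53 targets and the goblet genes went both ways and did not pass limma camera (adjusted p = 0.307, 0.283 and 0.4). The p53 target list gave 6 higher and 3 lower calls in 11, with the cell cycle inhibitor Cdkn1a 28.1-fold higher, and goblet genes gave 7 higher and 4 lower calls in 16, with the mucus protein Zg16 58.4-fold higher. Immediate early genes gave 8 lower and 2 higher calls (Junb and Zfp36) in 12, with Egr1 70.1-fold and Fosb 59.0-fold lower.

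Altogether 7876 of 12011 tested genes were called by limma, 4178 higher and 3698 lower in villus, and 6846 of them differed at least 2-fold. limma's camera passed 14 of 24 lists with the preset correlation and 0 with an estimated correlation, where the smallest adjusted p was 0.334 and 2 lists had an unadjusted p under 0.05. The 10 largest differences toward control ISC were all features under 200 bases listed at 0 in villus, such as Snord37 (53 bases, 75400 ± 95700 FPKM in control ISC). Per the labels, villus reads were 75 bases long and ISC reads 50. Snord37, Snord65, Scarna17, Mir3082, Mir3064 and Snord104 (53 to 73 bases) are shorter than a villus read. Their value of 0 in villus therefore cannot be told apart from an effect of read length. Of the 10 largest toward villus 5 were under 200 bases, such as Mir22 (95 bases, 4840 ± 1070 FPKM in villus and listed at 0 in control ISC). Of 43 calls above 8 on the log2 scale 25 were under 200 bases. The median of all tested genes was 0.104, -0.089 after quantile normalization and -0.012 with median scaling. Cell type cannot be separated here from the library preparation, since villus libraries were made from total RNA with another kit, instrument and read length than the polyadenylated RNA of the sorted ISC. Per the labels, ISC crypts were also disaggregated with an enzyme and sorted, which villus epithelium was not, and villus came from jejunum and ISC from the proximal small intestine. The differences in immediate early and distal intestine genes cannot be separated from these. With limma voom on recovered reads, the calls numbered 4061 of 6413 genes and 31.2% of them were higher in villus. The values used elsewhere gave 4098 calls on the same genes with 54.3% higher. Here voom scaled each library to its total of reads in these genes, which is not the scaling of the values used elsewhere. With quantile normalization 46.6% of all calls were higher in villus, against 53% in the main fit. The balance of directions in villus therefore depends on the scaling.

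**Figure D2:**
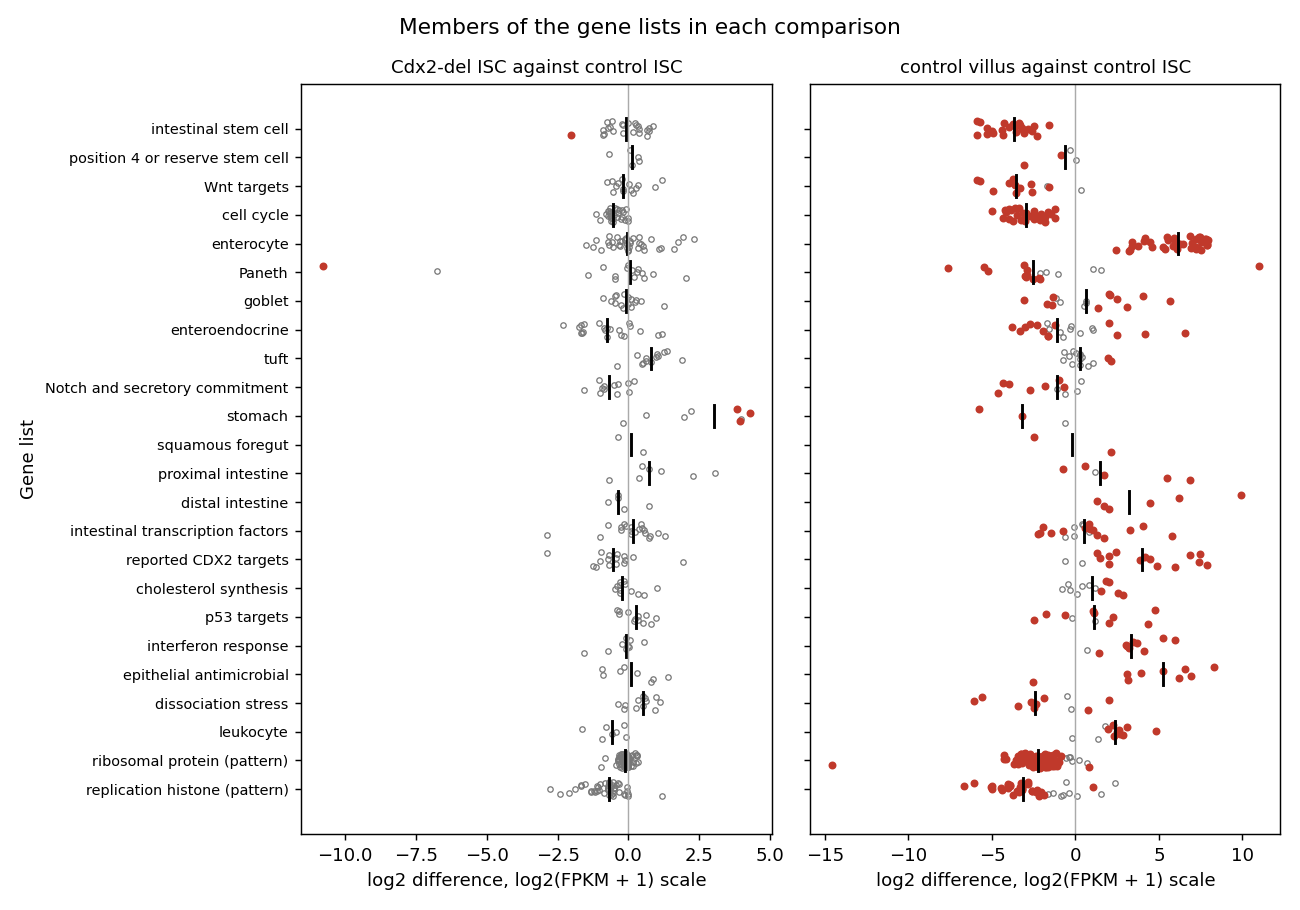
Log2 difference on the log2(FPKM + 1) scale (horizontal axis) of each tested member of each gene list (vertical axis) in Cdx2-del against control ISC (left) and villus against control ISC (right); filled points are genes with limma adjusted p under 0.05, open points are the others, and black bars are list medians. The stomach list has a median of 3.02 in Cdx2-del ISC, and the enterocyte list a median of 6.16 in villus.

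Whether the Cdx2-del differences follow the villus or the stem cell programme was described for genes at least 4-fold higher in either. Counting genes tested in both comparisons, of 1755 villus-high genes, 35.8% had a lower value in Cdx2-del than in control ISC, and of 1557 ISC-high genes, 73.0% did. Both comparisons use the same control ISC libraries, so all groups were simulated 100 times with shared controls and no change in Cdx2-del ISC. The simulations gave 43.2% (41.2 to 45.3) and 57.3% (54.9 to 60). Genes were drawn independently, so these ranges leave out shifts shared by the genes of a library and are too narrow to test the observed shares. With a library left out, the observed shares ran from 30 to 43.4% and from 64 to 78.4%. Without Cdx2-del library 0 the observed shares were 43.4% and 64.0%. Of all genes tested in both comparisons, 53.6% had a lower value in Cdx2-del ISC, against 50% (49.2 to 50.9) simulated. Across 11348 genes in both tests, which are not independent replicates, the log2 differences correlated at r = 0.286 against 0.141 simulated. Their covariance was 0.389 against 0.188 simulated, a difference of 0.201. Signs matched for 61.0% of genes against 53.6% simulated.

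Among the 9 higher Cdx2-del calls tested in both comparisons, 3 were also called higher in villus (Fmo1, Sepp1 and Foxq1) and 4 higher in control ISC than in villus (Fxyd3, Gkn3, Pgc and Sult1c2). Independent lists would give 3.0 and 2.9. Among the 6 lower calls, AI747448 was called higher in villus and Defa17 and Slc14a1 higher in control ISC, where independent lists would give 2.0 for each. The 3 control libraries cannot be split so that each part keeps a pair, so part of any excess may come from the shared controls.

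CDX2 was bound in ISC at 2389 sites in the authors' peak list (mm9), with a median width of 512 bases. The score is the authors' own value per peak and ran from 40.04 to 776.95 (median 67.34). The highest-scoring peak lay on chromosome 7 (74313142 to 74314491, score 776.95), 16.3 kb from the annotated 3′ part of Adamts17, a metalloprotease gene. The next lay on chromosome 18 (61435371 to 61436080, score 611.37, 12.6 kb from Pde6a), chromosome 8 (27766211 to 27767706, score 578.92, 158.1 kb from 2310008N11Rik), chromosome 1 (138257128 to 138258266, score 526.64, 50.8 kb from 9230116N13Rik) and chromosome 7 (90774928 to 90776406, score 500.22, 3.4 kb from Tmc3). Distances are to annotated 3′ parts of genes, since promoters and introns are outside the deposited annotation. Peak midpoints fell in an annotated exon part in 20 cases (0.8%, Wilson 95% interval 0.5 to 1.3%), and 67.8% (65.9 to 69.6%) lay within 50 kb of an annotated gene part.

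Genes for intestinal transcription factors often had a peak nearby. Of 20, 13 (65.0%, 43.3 to 81.9%) had a peak midpoint within 50 kb, against 12.9% of all genes in the table and 16.8% of the genes tested in Cdx2-del ISC. The 13 include Cdx1, Hnf4a, Isx and Cdx2 itself, with a peak of score 46.95 at 7.6 kb. The Notch and secretory list had 7 of 13 and reported CDX2 targets 8 of 16. The stem cell list had 8 of 24 and the enterocyte list 12 of 40. Immediate early genes, of which 8 of 12 had a peak, stood as high as the intestinal transcription factors. None of 21 stomach genes and none of 22 enteroendocrine genes had one, for which the Wilson upper bounds are 15.5% and 14.9%.

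**Figure D3:**
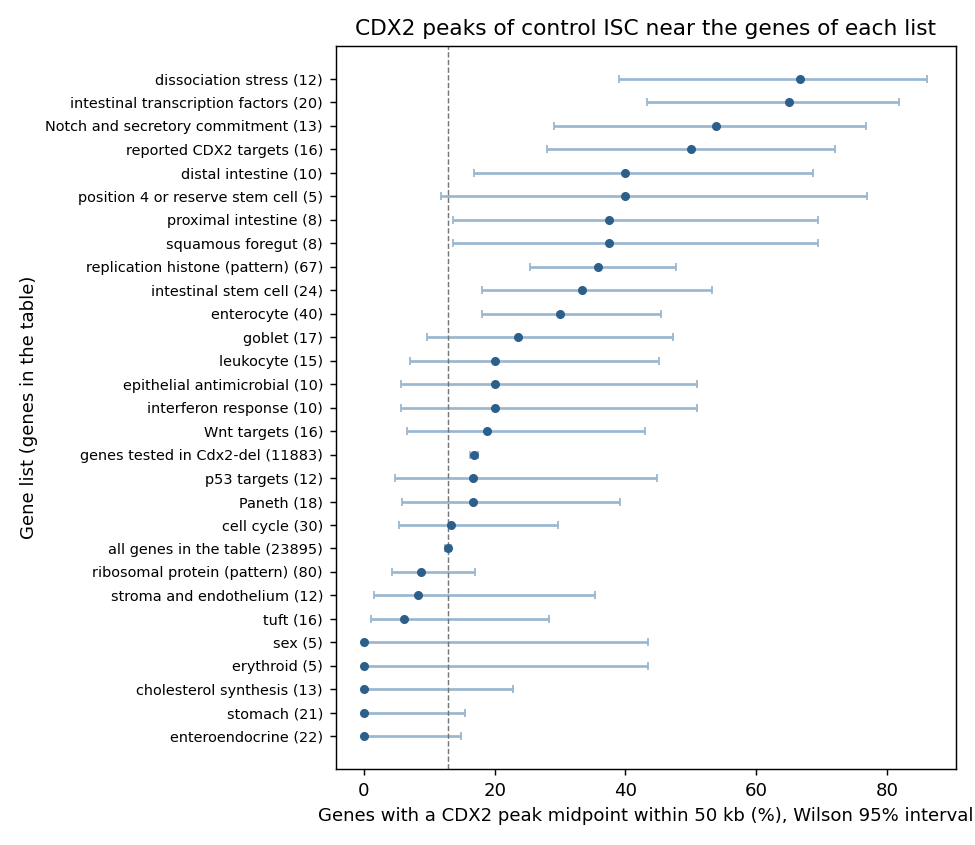
Percentage of the genes of each list with a CDX2 peak midpoint within 50 kb (horizontal axis), with Wilson 95% intervals as bars and the number of genes in parentheses; the dashed line marks the 12.9% of all genes in the table. Intestinal transcription factors stand at 65.0%, genes tested in Cdx2-del ISC at 16.8% and stomach genes at 0.

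Whether bound genes differed in the libraries labelled Cdx2-del was tested by Fisher's exact test (two-sided). The Fisher tests and random lists here and below take genes as independent, although neighbouring genes can share a peak. Their p-values and ranges do not measure variation between libraries, and the peaks come from 1 library. Of the 13 higher calls, 5 had a peak within 50 kb: Snord52, Scarb1, Sepp1, Foxq1 and Wfdc18. The odds ratio was 3.09 (95% interval 0.794 to 10.7, exact p = 0.0532) against 16.8% of the other tested genes, and it was 0.987 without Cdx2-del library 0, 0.981 without library 1, 1.24 without library 2 and 1.64 without control library 2. Of the 6 lower calls, Sept5 and Pkig had a peak (odds ratio 2.47, 0.223 to 17.2, exact p = 0.268). The nearest peak was 348.8 kb from Gkn3, 535 kb from Pgc, 618 kb from Clu and 1303.7 kb from Vsig1. With genes taken at unadjusted p under 0.01, the odds ratios were 1.72 (1.16 to 2.5, 39 of 152 higher genes, exact p = 0.00602) and 3.23 (2.01 to 5.12, 33 of 84 lower genes, exact p = 9.49e-07). The median absolute log2 difference of the 2002 tested genes near peaks was 0.340 in Cdx2-del ISC, above the 0.287 to 0.316 that holds the central 95% of 10000 random lists matched on mean expression. Their signed median was -0.003 (percentile 99.6 of the lists, whose central 95% ran from -0.049 to -0.008).

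Genes at least 4-fold higher in villus had CDX2 peaks of ISC nearby more often than other genes. Of 2016 such genes, 21.8% had a peak within 50 kb, against 15.9% of the other tested genes (odds ratio 1.47, 1.3 to 1.66, Fisher's exact p = 4.4e-10). Of 1557 genes at least 4-fold higher in control ISC 15.5% did, against 17.1% of the others, a difference that did not pass (0.893, 0.768 to 1.04, exact p = 0.137). With no fold minimum, 19.8% of 4178 genes called higher in villus had a peak, against 15.3% of the others (1.36, 1.23 to 1.5, exact p = 1.11e-09), and 14.2% of 3698 genes called higher in control ISC, against 18.1% (0.747, 0.670 to 0.834, exact p = 9.58e-08). At 5 kb and no fold minimum the odds ratios were 1.21 (exact p = 0.0993) and 0.850 (exact p = 0.203).

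The authors' deposited table marks 1087 genes as significant between Cdx2-del and control ISC, 668 higher and 419 lower in Cdx2-del, against 19 called here. It marks 18 of those 19 as significant in the same direction. For villus against control ISC the authors' deposited table marks 7152 genes, and 6614 of the 7876 limma calls are among them with the same sign.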

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

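No paired analysis was possible because nothing given links the column numbers to the replicate numbers of the labels, so the replicate block was not run for the comparisons, the Cdx2 level, the gene lists or the villus-high genes. The sex covariate, the removal of features under 200 bases, library weights, voom, the 4-fold minimum for the villus and control ISC peak tests, and the leave-one-out values of the villus-high shares and of the peak odds ratios were chosen after the data were seen. The cause was not tested for any change below unless it is stated. For the 19 calls in Cdx2-del ISC, the count was 0 with no filter on low values, 53 with all 9 libraries in the fit, 6 without a trend, 35 without features under 200 bases, 34 with library weights, and 9 to 14 with a library left out (fewer samples). Under both pseudocounts, the higher filter, both scalings and the sex covariate it was within 1.5 times of 19. With voom, run on 6372 genes of the most common length, it was 13 (6 higher and 7 lower), 4 of them among the 6 of the 19 calls that lie in those genes. Villus calls, 7876, numbered 4061 with voom on 6413 such genes, 4098 of which had been called without it. Villus minus control ISC in Cdx2 (0.81) became -0.04 with quantile normalization and -0.14 with voom. Tert (0.01) became -0.13 with pseudocount 5, -0.11 with median scaling and -0.91 to 0.57 with a library left out.

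Of the gene lists, 9 in Cdx2-del ISC became 0 with an estimated correlation and 2 with fry, and 14 in villus became 0 with an estimated correlation. Leaving out a library ended none of the 9 in Cdx2-del ISC. Lists that changed direction in some of those limma camera fits had adjusted p of 0.684 to 0.975 (position 4 or reserve stem cell), 0.684 to 0.888 (distal intestine), 0.169 to 0.991 (cholesterol synthesis), 0.0187 to 0.888 (sex), 0.00223 to 0.948 (enterocyte), 0.343 to 0.952 (interferon response), 0.0101 to 0.488 (Paneth), 0.0187 to 0.988 (goblet), 0.218 to 0.952 (Wnt targets), 0.00337 to 0.767 (leukocyte) and 0.35 to 0.888 (epithelial antimicrobial), and 0.405 to 0.977 for tuft in villus. The lowest came without control library 1 for enterocyte, without Cdx2-del library 1 for Paneth, goblet and sex, and without control library 2 for leukocyte. In single named genes, no direction turned in Cdx2-del ISC, with 837 values on the same side of the threshold, 71 no longer past it and 12 newly past it. In villus 1682 were on the same side.

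The villus-high share with lower values, 35.8%, was 38.7% at 2-fold and 30 to 43.4% with a library left out, and the ISC-high share, 73.0%, was 69.6% and 64 to 78.4%. Odds ratios for peaks near higher Cdx2-del calls, 3.09, were 1.72 at unadjusted p under 0.01 and 0.981 to 3.7 with a library left out. Near lower calls, 2.47, the odds ratio was 0 at 5 kb, 3.23 at unadjusted p under 0.01 and 1.97 to 4.97 with a library left out, and leaving out control library 1 gave no value because the 1 gene called had a peak. For genes called higher in villus (1.36) and in control ISC (0.747) it was 1.21 and 0.85 at 5 kb. With calls of at least 4-fold it was 1.47 and 0.893 (0.768 to 1.04), and the latter no longer passed. Fewer genes were called there, and the odds ratio itself was also nearer to no difference. The authors' 1087 significant genes in Cdx2-del ISC became 554 at q under 0.01. Depth limits low values most in villus library 2, where a single read was worth 0.689 FPKM.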

Other observations

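The tests of more duodenum and of the short length of Snord52 were chosen only after the result was seen, and the latter took the place of another test of the same explanation. The authors' deposited table also compares villus with Cdx2-del ISC directly. It marks 6912 genes as significant, 3650 higher in villus and 3262 higher in Cdx2-del ISC. Of the enterocyte genes 39 of 40 were higher in villus, as were 14 of 16 reported CDX2 targets and 9 of 10 interferon response genes. All 24 stem cell genes, 24 of 30 cell cycle genes and 68 of 80 ribosomal protein genes were higher in Cdx2-del ISC, and 5 stomach genes were, with none higher in villus.

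Villus libraries differed from each other in ileal genes. Fabp6 stood at 5900, 10600 and 1080 FPKM and the ileal bile acid transporter Slc10a2 at 43.7, 263 and 37.7 FPKM. Paneth cell genes differed between the sorted stem cell libraries of the same group. The lysozyme gene Lyz1 stood at 8760, 19700 and 1850 FPKM in Cdx2-del ISC and at 10700, 2600 and 11900 in control ISC, and the lectin gene Itln1 at 3000, 7650 and 424 FPKM in Cdx2-del ISC and at 3580, 924 and 7990 in control ISC. Cybrd1, a duodenal iron reductase, was between 6.68 and 13.6 FPKM in each Cdx2-del library and at most 0.581 in control ISC and 0.781 in villus.

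The remaining lists did not pass limma camera in Cdx2-del ISC. Medians were 0.13 for position 4 or reserve stem cells, -0.17 for Wnt targets, -0.08 for goblet, 0.17 for intestinal transcription factors, -0.21 for cholesterol synthesis, 0.28 for p53 targets, -0.08 for interferon response, 0.08 for epithelial antimicrobial genes, -0.57 for leukocytes and -0.11 for ribosomal proteins. The mixed test of fry, for changes in both directions, gave adjusted p = 2.32e-05 for intestinal transcription factors and 0.0475 for enterocyte genes. Of the intestinal transcription factors, the authors' deposited comparison marks 4 as higher and 3 as lower. Enterocyte genes had a median of -0.03 and a mean of 0.09, with camera's direction upward (adjusted p = 0.378). When adjusted over the list alone 4 enterocyte genes were higher, Apob (200 ± 35 against 41.9 ± 18.3 FPKM, limma adjusted p = 0.059 over all genes), Alpi, Anpep and Mogat2. The Paneth genes had a median of 0.05 and a mean of -1, with camera's direction downward (adjusted p = 0.403), and Defa17 and Defa3 passed as lower over the list alone. The sex list had a median of 0.02, or -0.01 after quantile normalization. In villus 10 of 24 lists did not pass, with medians of -0.60 for position 4 or reserve stem cells, 0.65 for goblet, 0.54 for intestinal transcription factors (-0.20 after quantile normalization), 1.10 for p53 targets, -1.08 for enteroendocrine, 0.27 for tuft, -3.20 for stomach, 1.45 for proximal intestine, 1.01 for cholesterol synthesis and 1.93 for sex. By fry for movement in 1 direction, 2 lists passed in Cdx2-del ISC, stomach and proximal intestine (adjusted p = 0.0092 for each), and 18 in villus. Of the squamous foregut list 2 genes were tested in each comparison, with 0 calls in Cdx2-del ISC and 1 in each direction in villus, and of the stroma and endothelium and erythroid lists 0 were.

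The count of 19 genes in Cdx2-del ISC was reached by 1 of the 10 splits of the 6 libraries, the real one, and the highest of the others gave 14. For villus 1 of 10 splits, the real one, reached 7876, and the highest of the others gave 1. With 10 splits no share under 0.05 can arise.

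Of 8 tested stomach genes 3 were called higher in Cdx2-del ISC, and the list did not pass with an estimated correlation (limma camera adjusted p = 0.0612). Stomach tissue carried over as a whole would bring its abundant transcripts. The median of 7 of them was 0.387 FPKM in Cdx2-del ISC and the highest, Atp4a, averaged 13.4, against 322 for Pgc. The cells had been sorted for high GFP driven by Lgr5, so these values cannot decide about stomach cells that carried this GFP. Variants linked to the floxed allele would cluster near Cdx2, and 0 of the 19 calls lay within 10 Mb of it, with 9.52% of the genes there at unadjusted p under 0.05 against 6.86% elsewhere (Fisher's exact p = 0.217). A larger share of duodenum also stays open. The proximal intestine list goes with it, with 6 of 7 members positive (fry adjusted p = 0.0092), Cybrd1 and Slc40a1 among them. That p is favoured by the filter, which Cybrd1 passed through the Cdx2-del libraries alone. Over all 8 genes of the list, tested or not, the mean log2 value per library was 4.419 to 4.811 in Cdx2-del and 3.601 to 3.91 in control ISC. The distal intestine list had a median of -0.37 over 5 tested genes, too few to decide. Deletion of Cdx2, which its measured level does not check, may raise part of a gastric programme, and none of the listed stomach genes had a CDX2 peak within 50 kb. Control ISC already held Gkn3 and Pgc transcripts, at means of 154 and 14.9 FPKM, against 2.4 and 0.911 FPKM in villus.

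Snord52 and Defa17 were each listed at 0 in every library of 1 ISC group and were high in the other. Another alpha-defensin, Defa3, split the same way, at 0 in each Cdx2-del library and at 164, 11.3 and 609 FPKM in control ISC. Short annotated length may lie behind Snord52: of the other tested features under 200 bases, 39.6% (63 of 159) had a control ISC library at 0 and another above 100 FPKM, against 0.04% of longer ones. No other short feature was at 0 in all libraries of 1 group and above 100 FPKM in all of the other (1 of 160, Snord52 itself), so this leaves the split by group open. For Defa17, reads shared between alpha-defensin copies cannot be told apart from a lower level, because the other 10 tested Defa genes summed to 3788 ± 3625 FPKM in Cdx2-del and 2697 ± 1736 in control ISC (SD, n = 3), a difference of 1091 that is smaller than this spread. A biological loss of Defa17 or Defa3 was not tested apart from the comparison itself.

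Ribosomal protein genes were lower in villus than in ISC libraries, by a median of -2.24 on the log2 scale. Non-ribosomal genes matched on annotated length and mean level did not share this, with a median of 0.45 (95% bootstrap interval -0.05 to 0.86). The matched genes can carry cell type differences of their own, so this does not exclude an effect of length. The kit and the RNA type, total in villus and polyadenylated in ISC, cannot be told apart from cell type, since each cell type had its own. A lower ribosomal programme in differentiated cells stays open and untested.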
